A study of Atriplex lentiformis with 9 samples.

How the data were processed

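The samples were roots of 9 quailbush plants (Atriplex lentiformis, a salt-tolerant shrub used to revegetate mine waste), taken after 11 weeks of growth in mine tailings mixed with 10, 15 or 20% compost (TC10, TC15 and TC20, 3 plants each). Per the labels' protocols, RNA was taken up with a plant column kit and total RNA libraries that keep the strand were made with a TruSeq kit. Per the submitters' processing notes, FastQC, Trim Galore, kallisto and DESeq2 were used. Their versions, the transcript reference and the way transcripts were given protein names are not given in the sources used here. The labels also give each plant's height, branch number, longest branch, a stress score whose scale is not explained, and the zinc, arsenic and lead content of its root.

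Each deposited file holds 1 normalised signal value per entry for 1 library, and the entries are names of Arabidopsis proteins, so an entry stands for the quailbush transcripts that were matched to that protein, and close paralogs are uncertain. In the deposited values every signal is a whole multiple of the value of 1 read: 100% of the values of each library came out as whole reads within 0.001 of a read after division by 1 factor per library. The files therefore hold read counts that the authors divided by a size factor. The factors gave 3030394 to 4752637 recovered reads in the 8 libraries used, and 4995 to 5055 entries were listed per library. No value of 0 is listed in a file, so an entry missing from a file was taken as 0. The union holds 5164 entries. Intervals and floors from these reads cover counting error only, because the reads carry no molecular identifiers. Neither a genome nor a table of gene names was used here, so no coordinates are given.

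The file of TC10 plant 5 was left out. Its column header names TC15 plant 6, and its 4995 entries are identical to those of TC15 plant 6, so the pair was counted as 1 sample, under TC15. The gene comparisons therefore rest on 8 libraries, 2 of TC10, 3 of TC15 and 3 of TC20. The plant measurements come from the labels and were used for all 9 plants.

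A count test had been chosen as the main test before the data were examined, with limma as the choice for normalised values. Since the deposited values are normalised, the main test was limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, on log2(value + 1) of the 4801 entries with a value of at least 10 in at least 2 libraries. Fold changes are on that scale, which understates the change of low entries. The 8 libraries shared 1 estimate of the spread. The tests were an F test of equal means in the 3 treatments, the 3 pairwise contrasts, and a slope per doubling of root zinc, arsenic or lead, each with Benjamini-Hochberg adjustment over the entries tested and a threshold of 0.05. The edgeR 4.0.16 quasi-likelihood test, limma-voom and DESeq2 1.42.0, whose likelihood ratio test is the test the series names, were run on the recovered reads as alternatives. DESeq2 was run without a prior filter on the real reads, and with the filter of the main test on simulated counts. An adjusted p below refers to limma unless another tool is named.

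Gene lists were fixed before the data were examined and matched to the entry names before any test. Of the 16 lists with a listed member, 14 had at least 3 tested members. The list of metallothionein, phytochelatin and nicotianamine synthesis genes had no listed entry, and the lists of nitrogen uptake and of green-tissue markers each had 2 tested members and were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 14 lists. A list score is the mean log2(value + 1) of its tested members in a library, centred on the 8 libraries. The named genes were set by rule before the data were examined: the entries past the threshold with the largest change (at a mean of at least 5 CPM and with groups that do not overlap) or the smallest p, list members past the threshold, the 6 entries with the smallest unadjusted p where fewer than 10 passed, and up to 8 members per metal list by mean abundance, at the same minimum. Entries whose name is only a locus code were not named by this rule. Plant measurements were compared with exact permutation tests of the F statistic over 1680 allocations and, per pair, of the difference of means over 20 allocations, two-sided, with a smallest possible p of 0.1 per pair. Correlations used exact permutation over all pairings (Python 3.11.15, scipy 1.17.1). For deviations from the treatment means the same shuffle gives only an approximate p, since deviations within a treatment are not independent. The principal components were computed again after each library was thinned at random to the lowest total, and without the 214 entries in the top 100 of any library, each scaled by the median of ratios. Other filters, scalings, a pseudocount of 0.1, a trend over compost percent, treatment as a covariate, each library left out in turn and the file of TC10 plant 5 as deposited were tried as well.

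The fits were tested on simulated counts with the means, depths and dispersions of the real libraries and 200 changed entries. The changed entries were drawn from those above a minimum mean value, so the shares found do not cover the lowest entries. Each entry was simulated independently, without the correlation between entries in the real libraries. The numbers of calls may therefore vary less than in real data. When TC20 differed from the other treatments, the limma F test on 4768 entries found 79% of 4-fold and 10% of 2-fold changes, with 5 false calls among 94. When TC10 differed, with its 2 libraries, the F test on 4772 entries found 61% of 4-fold and 5% of 2-fold changes. For TC20 against TC15 in the first simulation it found 77% of 4-fold and 14% of 2-fold changes. For a change of 2-fold per doubling of root zinc, the limma slope on 4764 entries found 89%. Root zinc ran from 174 to 1075 ug/g, so this change adds up to more than 2-fold over the libraries. The share is therefore not comparable with those for 2-fold changes between treatments. In 5 simulated sets without any change, the F test of limma called 0 to 1 entries, that of edgeR 0, and the likelihood ratio test of DESeq2 16 to 24.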

Results

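Roots of quailbush, a salt-tolerant shrub, were compared between mine tailings amended with 10, 15 or 20% compost (TC10, TC15 and TC20) after 11 weeks. The data consist of 7 measurements on each of 9 plants and of root RNA-seq values for 5164 entries named after Arabidopsis proteins. Expression was compared in 8 libraries, 2 of TC10, 3 of TC15 and 3 of TC20, because the file of TC10 plant 5 held the values of TC15 plant 6 in all 4995 entries. The libraries held between 3030394 (TC15 plant 6) and 4752637 (TC10 plant 2) recovered reads. Libraries of the same treatment were no more alike than libraries of different treatments: the median Spearman correlation was 0.953 over 7 same-treatment pairs and 0.953 over 21 pairs of different treatments. The labels name separate plants, so the p-values of the gene and plant tests measure the spread between plants. The camera p-values at the preset correlation compare entries with each other and do not measure that spread.

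The first question, which the series title raises, is how metals in the root varied with the treatment. Root zinc was 726 ± 290.5 ug/g in TC10, 671 ± 363 in TC15 and 222 ± 51.9 in TC20 (SD, n = 3 plants each), so the TC20 mean was 3.27-fold below TC10 and 3.02-fold below TC15, and each of the TC20 roots (174 to 277 ug/g) lay below each of the other 6 (373 to 1075 ug/g). Root arsenic was 253 ± 179, 123 ± 90.1 and 92.3 ± 23.7 ug/g, and root lead 115 ± 94.5, 34.3 ± 23.1 and 42.7 ± 14.6 ug/g in TC10, TC15 and TC20. Plants averaged 55.0 ± 3.61 cm in TC10, 74.3 ± 13.7 cm in TC15 and 76.7 ± 17.62 cm in TC20. The stress score was 2.00 in each TC10 plant, 3.67 ± 0.577 in TC15 and 2.33 ± 0.577 in TC20.

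None of the 7 measurements passed the exact permutation F test after adjustment. The lowest exact p was 0.0714, for the stress score, and that for zinc was 0.125, with an adjusted p of 0.245 for each. For zinc, the exact p of TC20 against TC10 and of TC20 against TC15 was 0.1, the smallest that 3 plants against 3 allow, and that of TC15 against TC10 was 0.8. The same exact p of 0.1, without overlap, was found for arsenic in TC20 against TC10 and for height and stress score in TC15 against TC10.

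**Figure D1:**
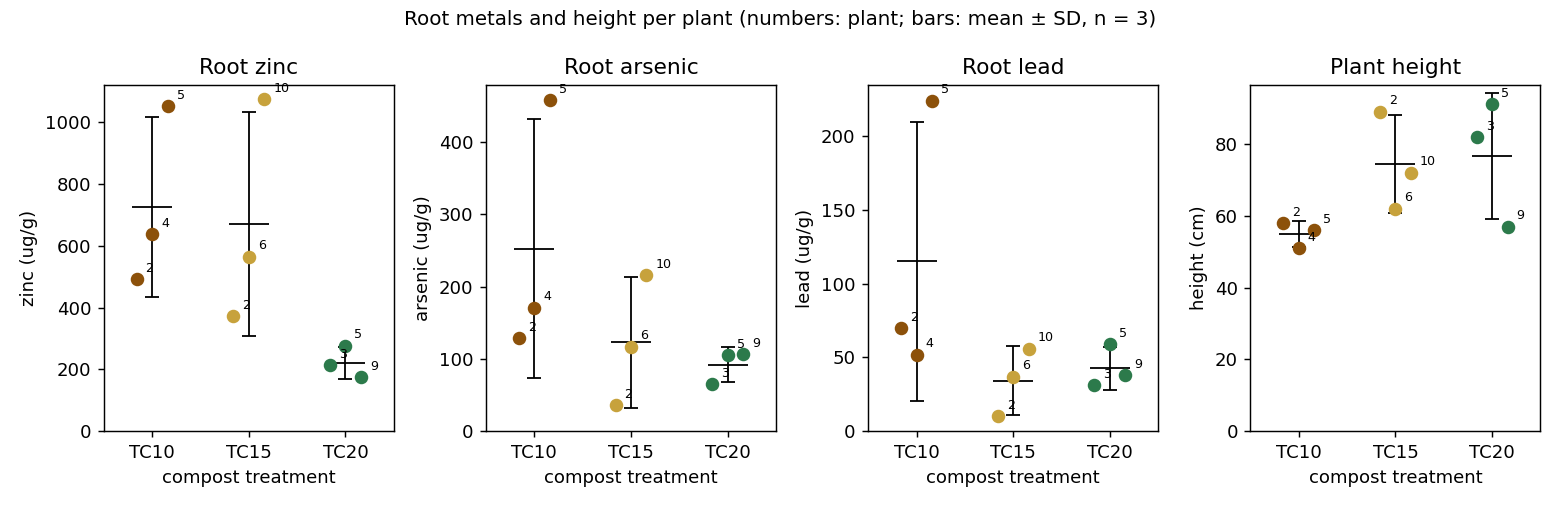
Root zinc, arsenic and lead (ug/g) and plant height (cm) of each plant by compost treatment, with points numbered by plant and bars for the mean and SD (n = 3). The 3 TC20 roots hold 174 to 277 ug/g zinc, below the 6 other roots, and the TC10 and TC15 roots overlap.

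Across the 9 plants, root zinc rose with root arsenic (Pearson r = 0.804, exact permutation p = 0.00297, adjusted over 6 relations 0.0178; Spearman rho = 0.817, exact p = 0.0108, adjusted 0.0646). Without the 2 plants farthest from the median zinc, r was 0.609 (exact p = 0.15), so the relation rests in part on those plants. Within treatments, as deviations from the treatment means, r was 0.887 (approximate permutation p = 0.00173). The relation of zinc with lead gave r = 0.633 (exact permutation p = 0.0514) and rho = 0.45 (exact p = 0.23). For lead, r was 0.274 (exact p = 0.552) without the same 2 plants and 0.745 within treatments (approximate permutation p = 0.0187). Height, branch number, longest branch and stress score had Pearson r from -0.376 to 0.429 with zinc, with exact p of at least 0.258.

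The series names a test of gene expression across the 3 treatments. In the limma F test of that question, the 6 entries with the smallest p, locus-coded names set aside, were TCX3, CSCL2, WAKLB, BABL, P2C05 and IPMKB, none of which passed with limma. CSCL2, a relative of the CSC1 cation channels that open under osmotic stress, had 2668 ± 339.7 normalised reads in TC10 (SD, n = 2), 544 ± 166 in TC15 and 716 ± 186 in TC20 (n = 3 each). WAKLB, a receptor kinase of the wall-associated family, had 914 ± 107, 517 ± 75.0 and 423 ± 26.7. P2C05, a protein phosphatase of class 2C, had 1083 ± 71.4, 545 ± 48.8 and 535 ± 116. IPMKB, an inositol polyphosphate kinase, had 309.6 ± 48.5, 344 ± 52.1 and 665 ± 110.3 in the same order. No entry reached an adjusted p of 0.05 with limma (lowest 0.104, for TCX3). Of 4801 entries, 247 had an unadjusted p under 0.05, where 240.1 are given by chance, and edgeR called 0 with 261 unadjusted. Here and in the comparisons below, leaving out a TC10 library leaves the other as the only one of that treatment. Its spread is then taken from the other groups, so such counts do not measure a difference between treatments. The 247 became 472 without TC10 plant 4, 149 without TC10 plant 2 or TC15 plant 6, and 143 without TC15 plant 2.

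With DESeq2, the likelihood ratio test called 35 entries of 5147 with an adjusted p, with TCX3, CSCL2, WAKLB, BABL, P2C05 and IPMKB among them (DESeq2 adjusted p from 3.8e-09 for CSCL2 to 0.0015 for P2C05). Of the 35, 11 had their highest mean in TC10 and lowest in TC20, and 7 their highest in TC10 and lowest in TC15. In some of these, such as ABAH1 and COBL7, named after their values were seen, the TC10 mean rested mainly on TC10 plant 2. In others, such as CSCL2 and WAKLB, it did not. The pattern can therefore not be read as one of treatment alone. From the called entries outside the naming rule, 2 further examples were chosen after their values were seen. AOX1A, the alternative oxidase of mitochondria, had 2102 normalised reads in TC10 plant 2, 325 in TC10 plant 4, 211 ± 48.6 in TC15 and 210.3 ± 108 in TC20, so its TC10 mean rests on 1 library. GOLS2, a galactinol synthase, had 196 ± 29.0, 137 ± 15.5 and 68.5 ± 24.3. The number called ranged from 18 to 231 when single libraries were left out (231 without TC10 plant 4, 71 without TC15 plant 10, 69 without TC20 plant 9, 23 without TC10 plant 2, 18 without TC15 plant 2 or plant 6), and 46 of 100 splits of the 8 libraries called at least as many.

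In TC20 against TC10, the entries with the smallest p, none of which passed with limma, included CSCL2 and WAKLB (log2 changes -1.93, SE 0.31, and -1.11, SE 0.18, adjusted p 0.70 each), IPMKB (1.1, SE 0.21, adjusted p 0.72), and P2C05 (-1.04, SE 0.20, adjusted p 0.72). SYT4, a synaptotagmin, had 1.91 ± 2.70 normalised reads in TC10 and 52.1 ± 34.8 in TC20, and DRL30, a probable disease resistance protein, 0.476 ± 0.674 and 32.0 ± 21.1. Of 4801 entries, limma passed 0 (206 with an unadjusted p under 0.05), edgeR called 0 with 220, and DESeq2 called 14, with CSCL2, WAKLB, IPMKB, P2C05 and SYT4 among them and not DRL30 (DESeq2 adjusted p 0.086). The 206 became 94 without TC10 plant 2 and 541 without TC10 plant 4, where limma called 2.

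In TC15 against TC10, the entries with the smallest p did not pass with limma either. FERON, a receptor kinase of root growth and wall sensing, had 5142 ± 478 normalised reads in TC10 and 2771 ± 245 in TC15 (log2 -0.89, SE 0.18, adjusted p 0.73). SAMC2, an S-adenosylmethionine carrier, had 84.3 ± 3.41 and 205 ± 24.4 (log2 1.27, SE 0.23, adjusted p 0.73), and RPD2B, a subunit of plant-specific RNA polymerases, 388 ± 117 and 909.9 ± 88.9 (log2 1.26, SE 0.23, adjusted p 0.73). CSCL2 had a log2 change of -2.33 (SE 0.31, adjusted p 0.19). Limma passed 0 (318 unadjusted), edgeR called 0 with 331, and DESeq2 called 22, with CSCL2, FERON, P2C05 and RPD2B among them. Without TC10 plant 4, which leaves 1 TC10 library whose spread is taken from the other groups, limma called 4. The 318 became 575 in that fit, 128 without TC10 plant 2 and 203 without TC15 plant 6.

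In TC20 against TC15, TCX3, a protein with cysteine-rich CXC domains that bind DNA, passed with limma (log2 6.00, SE 0.58, adjusted p 0.0426) and was higher in each of the 3 TC20 libraries than in each of the 3 TC15 libraries. The 3 TC15 values are all 0 and add no spread between plants to the shared estimate. The SE and p of TCX3 may therefore be too small. It had 0 reads in the 3 TC15 libraries, 63 in TC10 and 212 in TC20, so it was at least 69.9-fold higher in TC20 and at least 30.4-fold higher in TC10 than in TC15 when 3 counts over the TC15 libraries are taken as the floor. The bound for TC20 was 44.9-fold without TC20 plant 9, which held the highest value (127.0, against 41.5 and 47.2), and 45.1-fold, 51.1-fold and 43.7-fold without TC15 plants 2, 6 and 10. The bound for TC10 was 19.6-fold without TC15 plant 2 and 19.0-fold without TC15 plant 10. TCX3 was the 1 entry at 0 in a whole treatment with a value of at least 10 in each other library, and 45 of 100 splits of the 8 libraries, the real one included, gave at least 1 such entry (highest other 3). The call was lost without any 1 of the 8 libraries (adjusted p from 0.107 without TC15 plant 10 to 0.275 without TC20 plant 5), edgeR called 0 with 295 unadjusted, and DESeq2 called 11 with TCX3, BABL, HSFC1, NFYB3, P2C16 and IPMKB among them (DESeq2 adjusted p from 9.6e-07 for TCX3 to 0.015 for IPMKB). Limma gave 280 entries with an unadjusted p under 0.05, 134 without TC15 plant 2 and 182 without TC15 plant 6. BABL, a small blue copper protein, had 1775 ± 318 normalised reads in TC15 and 4156 ± 863 in TC20 (log2 1.22, SE 0.21, adjusted p 0.79). HSFC1, a heat stress transcription factor, had 1678 ± 719 and 443 ± 110.05 (log2 -1.83, SE 0.37, adjusted p 0.79), NFYB3, a subunit of a CCAAT-binding factor, 1578 ± 236 and 639 ± 143, and P2C16, a phosphatase that restrains abscisic acid signalling, 461 ± 289 and 66.5 ± 28.4.

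**Figure D2:**
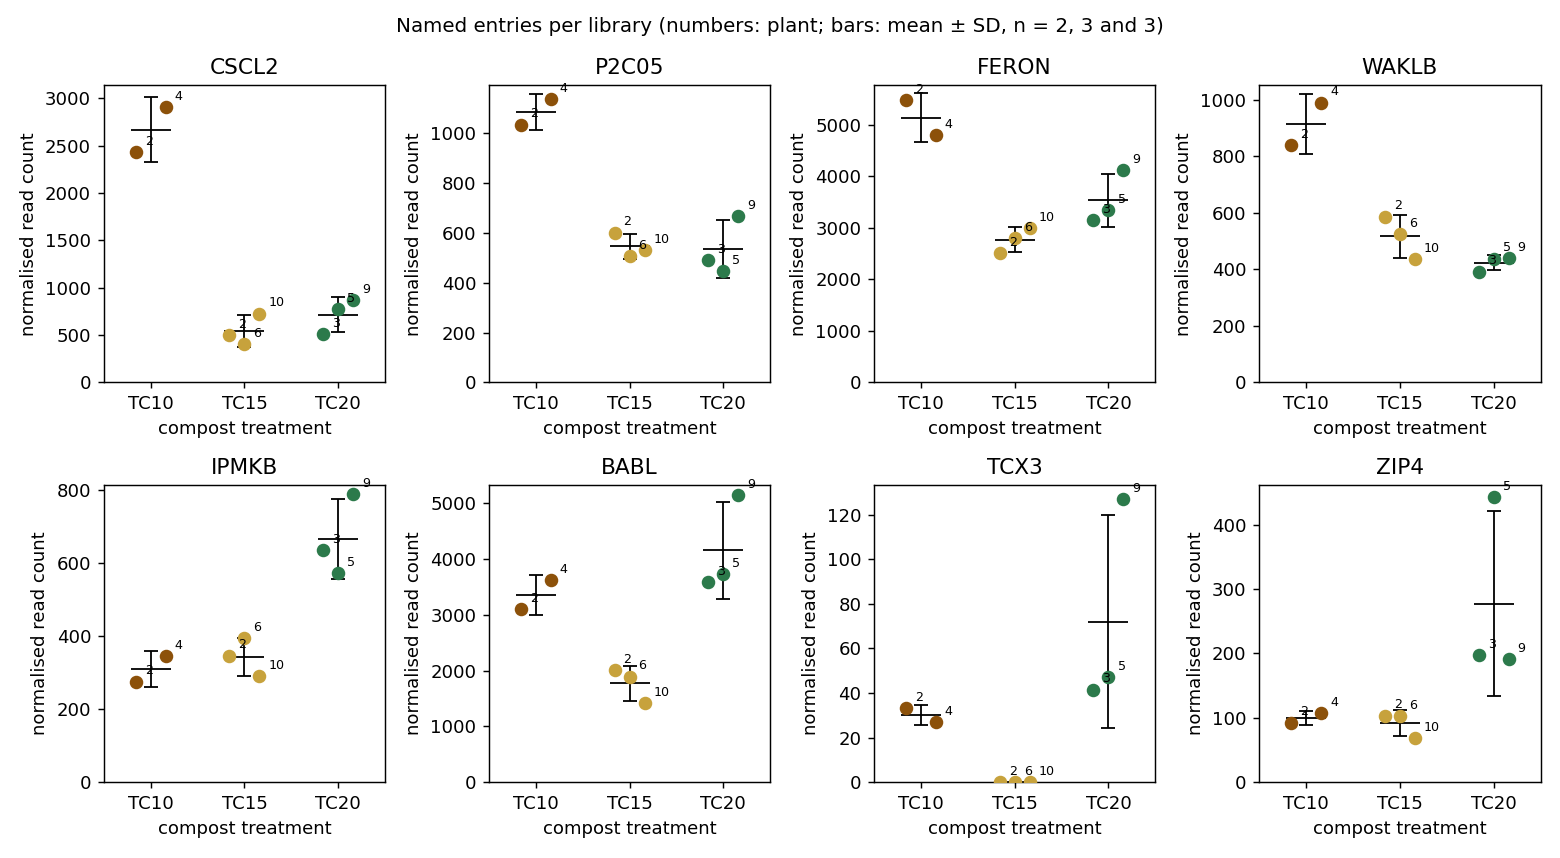
Normalised read counts of 8 named entries in each library by compost treatment, with points numbered by plant and bars for the mean and SD (n = 2, 3 and 3). CSCL2 lies at 2428 and 2908 in the TC10 libraries and between 404 and 865 in the others, and TCX3 is at 0 in the 3 TC15 libraries.

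Of 3 tested zinc and iron uptake transporters of the ZIP family, none passed over all entries in any comparison. ZIP4, a zinc uptake transporter, had 100.2 ± 10.9 normalised reads in TC10, 91.6 ± 20.5 in TC15 and 277 ± 144 in TC20. It was highest in the 3 TC20 libraries (191, 198 and 443, against 67.9 to 108 elsewhere). Its adjusted p was 0.81 across treatments over all entries, it passed adjusted over the list alone, and DESeq2 gave 0.0257. ZIP4 also passed adjusted over the list alone in TC20 against TC10, in TC20 against TC15 and on the zinc slope, and the list as a whole had an adjusted camera p of at least 0.0936 in limma. ZIP1 had 120.5 ± 58.5, 205 ± 90.0 and 252 ± 34.7, and ZTP50, a putative zinc transporter, 693 ± 5.48, 637 ± 112 and 624 ± 53.3. Over 8 plants, ZIP4 on the log2 scale was negatively related to log2 root zinc, short of the threshold after adjustment (Pearson r = -0.75, exact permutation p = 0.0295, adjusted over 2 measures 0.0589; Spearman rho = -0.738, exact p = 0.0458, adjusted 0.0917). Without the 2 plants farthest from the median zinc, r was -0.714 (exact p = 0.101). Within treatments it was -0.025 (approximate permutation p = 0.955), but 2 or 3 plants per treatment cannot exclude a relation there. ZIP4 had passed over its list alone on the zinc slope in the same 8 libraries, so this relation is not separate support. The other measure in the adjustment was the list score of cytosolic ribosomal proteins, and no further genes or lists were counted.

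Of 37 tested metal export, storage and long-distance transport genes, none passed over all entries or adjusted over the list alone in a pair or on the zinc slope, and the list had an adjusted camera p of at least 0.265 in limma. MTP1, which loads zinc into the vacuole, had 1054 ± 217 normalised reads in TC10, 1362 ± 116 in TC15 and 1007 ± 308 in TC20. HMA5, a copper-transporting ATPase, had 1275 ± 249.7, 1212 ± 275 and 1001 ± 170.3. ZIFL1, of the zinc-induced facilitator family, had 4459 ± 169, 5422 ± 1221 and 3675 ± 893, and YSL6, a metal-nicotianamine transporter, 775 ± 2.13, 677 ± 50.1 and 848 ± 78.3. The oligopeptide transporter OPT4 and the ABC transporters AB14C, AB3C and AB5C had adjusted p of at least 0.81 across the treatments.

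Cytosolic ribosomal protein genes had a mean log2 change of 0.35 in TC20 against TC10 (33 of 35 members positive), which passed with camera in limma at the preset correlation (adjusted p = 5.4e-09) and not with an estimated correlation (adjusted p = 0.67) or with fry (adjusted p = 0.63). Against TC15 it was 0.24 (32 of 35 positive), with adjusted p of 0.00013, 0.58 and 0.52 in limma in the same order. The mean slope was -0.14 per doubling of zinc (33 of 35 negative), with adjusted p of 1.5e-06, 0.66 and 0.54 in limma. In exact permutation tests of the list score, p was 0.3 for TC20 against TC10 and 0.5 for TC20 against TC15, where 0.1 is the smallest possible. No member passed by itself. TC20 plant 9 had the highest list score (0.57, against -0.28 to 0.13 in the others). Without it the mean log2 change was 0.15 against TC10 (adjusted p = 0.0044), 0.04 against TC15 (adjusted p = 0.43) and 0.02 per doubling of zinc (adjusted p = 0.98). Without TC15 plant 2 it was 0.13 against TC15 (adjusted p = 0.076).

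Heat shock proteins and factors were lower as a list in TC15 than in TC10 (mean log2 -0.50, 18 of 28 members negative, adjusted camera p = 0.038; adjusted p = 0.72 with an estimated correlation). With fry the adjusted p was 0.62 in limma. Named after their values were seen, the small heat shock protein HS181 had 4294 normalised reads in TC10 plant 2, 1473 in TC10 plant 4 and 467 ± 290 in TC15, and the chaperone HS901 12044, 2951 and 1649 ± 497. Neither passed over all entries. The list score was 0.57 in TC10 plant 2 and 0.06 in TC10 plant 4. HSFC1 was among the 10 members with a positive change, and it passed adjusted over the list alone in TC20 against TC15. Without TC10 plant 2 the mean log2 of the list was -0.25 and the adjusted p 0.32, and the call was also lost without TC15 plant 2 (adjusted p 0.07), TC15 plant 6 (0.115), TC20 plant 3 (0.072) or TC20 plant 9 (0.05002). The fall from TC10 is not particular to TC15. In TC20 against TC10 the list had a mean log2 of -0.34 (20 of 28 members negative). Its adjusted camera p there was 0.079, and 0.74 with an estimated correlation. No other tested list passed with camera in a pair: phosphate and arsenate transport (23 members), iron homeostasis (6), antioxidant enzymes (24), sulfur (8), salt and abscisic acid responses (6), defence (11), lignin and suberin (13), aquaporins (5), organelle-encoded entries (7) and reference genes (5). Apart from the salt and abscisic acid list, these had an adjusted camera p of at least 0.12 in the pairs with limma. The salt and abscisic acid list had a mean log2 of -0.85 in TC20 against TC10 (0 of 6 members positive, adjusted p = 0.094 with camera, 0.47 with an estimated correlation and 0.041 with fry in limma), and a median of -0.29. Its members COR47, a dehydrin, and LTI65, a protein induced by abscisic acid, named after their values were seen, had 111 ± 64.5 and 707 ± 131 normalised reads in TC10, and 22.1 ± 15.7 and 326 ± 415 in TC20.

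Against root zinc, none of 4801 entries passed with limma (204 with an unadjusted p under 0.05), edgeR called 0 with 237, and DESeq2 called 6, with USPL1, R47BP, IPMKB, BXL7 and RBL1 among them (DESeq2 adjusted p from 5.0e-07 for USPL1 to 0.034 for IPMKB) and not U86A1 (0.069). The 204 became 103 without TC20 plant 9, and with treatment as a covariate it was 590, with 1 entry (VITH4, named after its values were seen) past the threshold. USPL1 had the smallest p with limma, with a slope of 0.70 per doubling of zinc (SE 0.10, adjusted p 0.28). R47BP, an RNA-binding protein, had 0.46 (SE 0.09, adjusted p 0.92). IPMKB (-0.56, SE 0.12), BXL7, a xylosidase of the cell wall (-0.36, SE 0.08), RBL1, a rhomboid-like protein (-0.67, SE 0.14), and U86A1, a glycosyltransferase (-0.73, SE 0.17), had negative slopes with adjusted p of 0.92. For arsenic limma passed 0 (245 unadjusted, 97 without TC15 plant 2 and 379 without TC10 plant 2), edgeR 0 with 235 and DESeq2 6, with IDD3 among them. For lead limma passed 0 (330 unadjusted, 521 without TC10 plant 2 and 254 without TC15 plant 2, lowest adjusted p 0.0607, for IDD3). For the same slope edgeR called 2, IDD3 and the locus-coded M030, and DESeq2 42. Limma-voom called 4, with IDD3 and CCMC among them. CCMC, an entry encoded in the mitochondrial genome, was highest in TC15 plant 2. The slope of IDD3, a zinc finger protein of the INDETERMINATE DOMAIN family, was -0.56 per doubling of lead (SE 0.06), and its highest value, 1495, was in TC15 plant 2, the root with the least lead (10 ug/g) and the highest score of organelle-encoded entries (2.1).

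**Figure D3:**
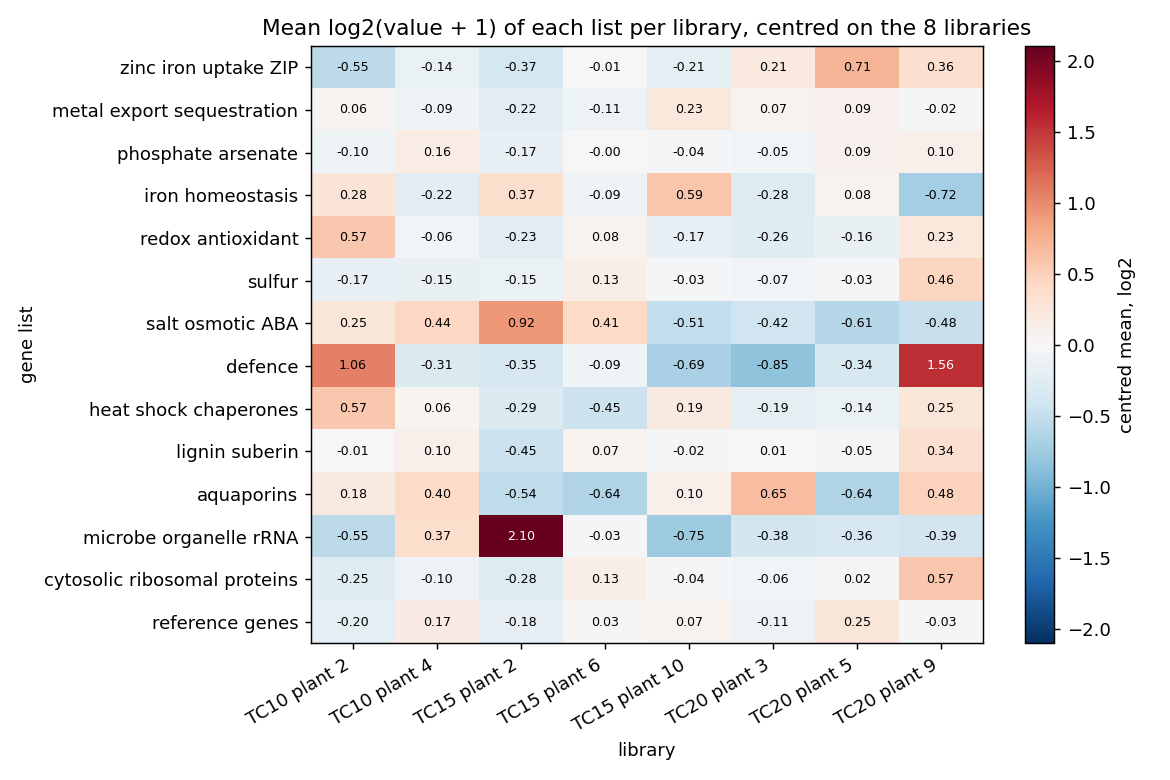
Mean log2(value + 1) of each gene list in each library, centred on the 8 libraries, for the 14 lists with at least 3 tested members. TC10 plant 2 and TC20 plant 9 have defence scores of 1.06 and 1.56, with the other 6 between -0.85 and -0.09, and also the highest heat shock (0.57 and 0.25) and antioxidant scores (0.57 and 0.23).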

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

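The choice of test changed the gene counts more than filters or scaling did. The alternatives chosen after seeing the data were edgeR with TMM factors, the limma fits with other filters, the file of TC10 plant 5 as deposited, the fits without TC10 plant 2 and TC20 plant 9, the other fits of the DESeq2 test, upper-quartile and TMM factors for the lists, and a metal list without oligopeptide and ABC transporters. DESeq2 called 35 entries across treatments, 14 in TC20 against TC10, 22 in TC15 against TC10, 11 in TC20 against TC15, and 6, 6 and 42 for zinc, arsenic and lead, where limma passed 0, 0, 0, 1, 0, 0 and 0. In simulated data without change it called 16 to 24 across treatments. In simulated data with 200 changed entries its false calls in TC20 against TC10 were 22 among 134 and 32 among 155. They were 21 among 140 in TC15 against TC10, 21 among 154 in TC20 against TC15 and 27 among 217 for zinc. No data without change were simulated for the pairs or zinc, so these numbers give no chance level for the real calls. For arsenic and lead the cause was not tested. The 35 became 3 with the file as deposited and 18 to 231 with 1 library left out; the numbers of shared entries were 3, and 12 to 27. Across treatments limma called 1 without a filter and 0 to 1 with 1 library left out, 0 to 2 in TC20 against TC10 and 0 to 4 in TC15 against TC10. The highest of each came without TC10 plant 4, which leaves 1 TC10 library. For zinc, treatment as a covariate gave 1, with 590 entries under an unadjusted p of 0.05, where there were 204 without it. For lead, each of the 5 edgeR fits gave 2, limma-voom 4, and leaving out 1 library 0 to 2 (2 without TC10 plant 2, 1 without TC20 plant 3 or plant 5). The cause was not tested.

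The 1 call in TC20 against TC15 became 0 in each edgeR fit, in limma-voom, with a mean value of 50 or more (which removes TCX3), in the libraries of the pair alone, with the file as deposited, without the 2 libraries that stand apart, and without any 1 library. The log2 change of TCX3 was positive in each of these fits that tested it. Its 0 reads in each TC15 library fix that sign in advance, so the sign is no separate support.

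For the gene lists, an estimated correlation gave 0 in each of the 4 comparisons, where the preset one gave 1 in each, and leaving out the 2 libraries that stand apart gave 0 in each. Fry gave 0 in TC15 against TC10, in TC20 against TC15 and on the zinc slope, and 1 in TC20 against TC10, which was the salt and abscisic acid list; the ribosomal protein list had an adjusted p of 0.63 there. Leaving out 1 library gave 1 to 4 lists in TC20 against TC10, 0 to 3 in TC15 against TC10 and in TC20 against TC15, and 0 to 2 on the zinc slope; upper-quartile factors gave 2 in TC20 against TC10. The mean ribosomal protein slope on zinc turned to 0.0162 without TC20 plant 9 (from -0.220 to 0.0162 over the libraries left out) and to 0.0217 without both that library and TC10 plant 2, so its sign rests on TC20 plant 9. Its direction in the pairs was upward under each scaling tried.

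The plant measurements passed 0 of 7 under each alternative. The 1 relation of zinc past the threshold became 0 without the 2 plants farthest from the median, and the correlation with the longest branch turned to 0.187 within treatments. No paired analysis was possible because the treatments share fewer than 2 plant numbers. With 2 or 3 libraries per treatment, 2-fold changes were mostly not detectable in simulated data.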

Other observations

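The tests in this part were chosen after the results were seen, except that the outcomes of the principal components on thinned reads and without abundant entries were not yet known. In the defence list fixed before the data were examined, some members, named after their values were seen, differed between single libraries, and no test of the list by library was made. TIF5A, a repressor of jasmonate signalling, had 517 normalised reads in TC10 plant 2 and 559 in TC20 plant 9, and 2.46 to 17.5 in the other 6 libraries. TIF9, of the same family, had 519 and 2598, against 59.7 to 235 elsewhere. The chitinase CHI5 reached 11095 in TC20 plant 9, against 632 to 3015 elsewhere, and the transcription factor WRK33 13571 in TC10 plant 2, against 2368 to 6205 elsewhere. EDS1L and EDSBC, which act in salicylate defence, were lowest in TC20 plant 9 (483 and 211). Entries encoded in the mitochondrial genome were high in TC15 plant 2, where CCMC had 199 normalised reads, against 11.5 to 39.3 elsewhere, and NU6M 139.9, against 7.09 to 22.1.

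TC10 plant 2 and TC20 plant 9 lay at -40.7 and -29.8 on the first principal component, which held 26.8% of the variance, and the other 6 between 1.32 and 25.9. The 2 libraries lay on opposite sides of the second component (-15.4 and 32.8) and of the third (27.4 and -21.6). Their Spearman correlation with each other was 0.944, where TC10 plant 2 had 0.934 with TC15 plant 10 and 0.953 with TC10 plant 4. A cause shared by the 2 is therefore not shown. TC10 plant 2 was the deepest library and had the highest share of reads in its top 10 entries (6.36%, against 3.57 to 4.71% in the other 7), but depth and a few abundant entries are argued against as the whole cause: the gap between the 2 libraries and the nearest other stayed at 30.7 with reads thinned to the lowest total (SD of the other 6, 8.61) and at 33.8 without the top 100 entries of any library (SD 8.08), from 30.8 with all reads. A candidate explanation is a higher expression of defence genes in these 2 roots, whose lower defence score was 1.06, with the other 6 below 0. The test is not particular to defence, since the same libraries had the highest scores of the heat shock (0.57 and 0.25), antioxidant (0.57 and 0.23) and nitrogen (0.72 and 0.70) lists, so which genes set them apart stays open. The plants come from different treatments, so the design names no group that would set them apart.

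The 35 entries called by DESeq2 across treatments were reached or exceeded in 46 of 100 splits of the 8 libraries, the real one included, so chance cannot be excluded. The highest other split gave 356 and grouped TC10 plant 2 with TC20 plant 9, and the next gave 339 and grouped TC10 plant 2 with TC15 plant 2 (13 calls with limma, against 5), so the splits point to a structure of the samples apart from treatment that is not particular to 1 pair. Too many calls by the test in small groups may add to this, since it called at least 16 entries in each simulated set without change. With limma, 33 of 100 splits gave as many as 247 entries under an unadjusted p of 0.05, and the highest other gave 625. For TC20 against TC15, 10 splits are too few for a share under 0.05: 2 splits gave 1 call with limma (highest other 1), and 9 gave at least 1 passing list (real 1, highest other 5).

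The file of TC10 plant 5 equals that of TC15 plant 6 in 4995 of 4995 entries. One RNA sample sequenced in 2 libraries is argued against, since the chi-square per entry between the files was 0, where sampling noise would give about 1, and the lowest between other libraries was 26.4. A candidate explanation is that the column of TC15 plant 6 was written to both files, since the header in each names TC15 plant 6. The labels give TC10 plant 5 a root zinc of 1051 ug/g and TC15 plant 6 one of 565 ug/g, so the plants are not the same in the measurements.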
